A study of Homo sapiens with 30 samples.

How the data were processed

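RNA sequencing was measured in 30 samples in 10 groups of 3: whole-cell poly(A) RNA of Hues6 human embryonic stem cells, wild type (WT) or labelled QKI knockout (KO), at days 0, 4 and 8 of differentiation to cardiomyocytes (D0, D4, D8); nuclear RNA of both genotypes at D8; and 293T cells, an embryonic kidney line, given a control siRNA or an siRNA against QKI. Per the labels, the days after D0 followed 1.5 uM CHIR, a GSK3 inhibitor that activates WNT signalling, in WT and 1.25 uM in KO, with 1.5 ng/mL BMP4 in both. RNA was extracted with Trizol and libraries of the differentiating cells were made with stranded mRNA kits; the 293T libraries followed a protocol derived from crosslinking assays.

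The authors deposited 2 tables of read counts per gene, one for the 18 whole-cell libraries and one for the 6 nuclear libraries, with no normalisation. The values are whole numbers with a different total in each library. The submitters' notes name UMI-tools, cutadapt, STAR, featureCounts, DESeq and the build hg19; their versions, the strand setting and the annotation release are not given in the sources used here. The authors also deposited 4 skipped-exon tables in the format of rMATS, for D0, D4, D8 and 293T, whose values are junction read counts, inclusion levels between 0 and 1, p-values and FDR. The rMATS version is not given in the sources used here. Each table compares a first arm of 3 libraries with a second arm of 3, and names neither arm. Recomputed from the levels per library, all deposited differences were equal to first minus second within 0.002; they are given here as second minus first.

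Total counts ran from 40001076 to 89948185 in the whole-cell libraries and from 6549676 to 15030590 in the nuclear ones. The whole-cell table lists 39126 genes, and 55548 genes are listed for nuclear RNA. Gene symbols of 38917 nuclear identifiers came from the whole-cell table and 14147 from a reference table of gene names, which left 2484 without a symbol.

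Counts were fitted in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors and the quasi-likelihood test, with 1 mean per group. All 18 whole-cell libraries shared 1 fit (21761 genes, biological coefficient of variation 8.23%), and the 6 nuclear libraries had their own (30481 genes, 11.9%). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. Values per gene are CPM (over TMM-scaled totals), as the mean ± SD of 3 libraries, and log2 fold changes carry standard errors (SE). The comparisons were KO against WT at D0, D4 and D8 and in nuclear RNA, WT D4 against D0, WT D8 against D4, and the difference between the KO effects of successive days as an interaction.

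The method was tested on counts simulated for each KO comparison, with changes of known size, and not on the measured counts themselves. Of genes changed 2-fold, 95.5% were recovered at D0, 91% at D4, 98.5% at D8 and 89.6% in nuclear RNA; of genes changed 1.5-fold, 70.1%, 62.7%, 79.1% and 37.3%. False calls numbered 12, 14, 7 and 2. These rates describe the simulated counts. The spread between the measured libraries may differ, so the rates may not hold for them. For a gene whose group held no count, the fold is a bound against a floor of 3 counts over the group. With 1 to 3 counts it is a ratio with a 95% counting interval. Intervals and floors cover counting error only.

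In all, 25 gene lists were fixed before the data were examined: pluripotency, primitive streak, cardiac progenitor, cardiac sarcomere, calcium handling and ion channels, cardiac energy metabolism, endoderm, neural, endothelial, smooth muscle and fibroblast, epicardium, surface ectoderm and amnion, presomitic mesoderm, WNT response, BMP and TGF-beta response, proliferation, p53 response, endoplasmic reticulum and amino acid stress, hypoxia and glycolysis, U4/U6.U5 tri-snRNP proteins, U1 snRNP and associated proteins, muscle and tissue splicing regulators, mitochondrially encoded, extracellular matrix and adhesion, and muscle and cytoskeletal splicing. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 25 lists; camera compares a list with the other genes. Some genes are in more than 1 list, so list results are not independent.

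A skipped-exon event was called at the authors' FDR under 0.05, an absolute difference in inclusion of at least 0.1 and a mean of at least 10 junction reads per library in each arm. Events that share an exon but differ in its neighbours count separately. Overlaps between tables and shares of genes were compared with two-sided Fisher's exact tests, Benjamini-Hochberg adjusted within each family. As a second test, limma was run on the logit of inclusion per library (levels bounded at 0.01); on 5000 simulated events, 186 of 200 differences of 0.2 at 100 reads were recovered (93%), with 7 false calls.

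Genes and events were named by a rule set before the data were examined. Per KO comparison it named QKI, and the 5 highest and 5 lowest log2 fold changes among called genes with at least 10 CPM on average and no overlap between the genotypes. It also named up to 3 members of each list with the smallest p. Per splicing table it named the 5 largest rises and falls, 1 event per gene, up to 6 events of the muscle and cytoskeletal splicing list, and up to 8 events called with the same sign in the most tables. Any other gene is marked as chosen after its values were seen. Some genes and events that the rule named are not reported here.

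Alternatives chosen before the data were examined were DESeq2's size factors, total counts without TMM, no low-count filter, only the libraries compared, the DESeq2 1.42.0 Wald test, the replicate number as a block, an added 2-fold threshold, each replicate left out in turn, camera with an estimated correlation or with the block, fry, other limits on the splicing calls, and limma in place of the authors' FDR. Fisher's exact tests of splicing used scipy 1.17.1 with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots matplotlib 3.10.9. Fisher's exact test of imprinted genes was run in R. Residuals of KO and WT libraries with the same replicate number correlated at 0.302, -0.356 and 0.475 at D0 and from -0.00671 to 0.0988 at D4. At D8 these values were 0.104 and -0.291, and in nuclear RNA -0.185 to -0.00968. Different numbers gave -0.584 to 0.452 at D0, -0.187 to 0.125 at D4, -0.428 to 0.444 at D8 and -0.0172 to 0.193 in nuclear RNA. So few pairs neither show nor exclude pairing by number. No column of values per sample was left unused (0 columns). The 293T libraries have no count table among the sources used here, so their gene expression, the strength of 5' splice sites and QKI binding motifs at the exons were not analysed here.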

Results

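Poly(A) RNA was sequenced from Hues6 embryonic stem cells, WT or labelled QKI KO, at D0, D4 and D8 of cardiomyocyte differentiation, with 3 libraries in each of the 6 groups. A further 3 libraries per genotype held D8 nuclear RNA, and 293T cells with a control or a QKI siRNA gave 3 libraries each. Whole-cell libraries held 48697867 to 61484118 counts at D0, 40001076 to 53030999 at D4 and 62162704 to 89948185 at D8. Nuclear libraries held 9882089 to 15030590 in KO and 6549676 to 8896202 in WT. The labels do not say whether the libraries of a group come from separate cultures, so the p-values measure only the spread between these samples. At D4 and D8, CHIR dose differed along with genotype, so every KO difference after D0 is also a difference in dose.

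QKI, an RNA-binding protein that controls splicing in muscle and glia, was measured first in every library. Its level (ENSG00000112531.12) at D0 was 293 ± 7.4 CPM in WT and 39.4 ± 3.3 in KO (SD, n = 3), a log2 fold change of -2.90 (SE 0.10, edgeR adjusted p 7e-15). At D4 it was 146 ± 8.9 in WT and 78.2 ± 10 in KO (-0.90, SE 0.09, edgeR adjusted p 1.6e-07). At D8 it was 324 ± 42 in WT and 335 ± 5.3 in the libraries labelled KO, which were not told apart (0.05, SE 0.09, edgeR adjusted p 0.66). The D8 estimate ran from -0.08 to 0.15 over all alternatives. In D8 nuclear RNA QKI was higher in the libraries labelled KO, 505 ± 31 against 160 ± 25 CPM (1.66, SE 0.17, edgeR adjusted p 7.9e-10).

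**Figure D1:**
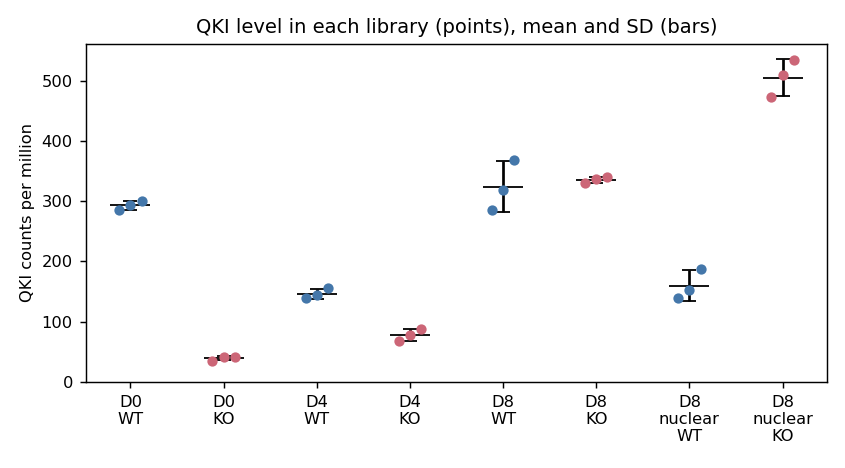
QKI CPM in each library (points), with the group mean and SD (bars), for WT (blue) and KO (red) at D0, D4 and D8 and in D8 nuclear RNA. The KO libraries sat at 35.5 to 41.3 at D0 and 68.2 to 88.5 at D4, below every WT library, but at 329 to 340 at D8, inside the WT range of 285 to 368, and at 473 to 534 in nuclear RNA.

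QKI junction reads of the authors' deposited tables were compared after scaling to the total of each arm. In the authors' deposited table for D0, the second arm stood at 4.18 to 8.24% of the first, over 4 skipped-exon events. In the authors' deposited table for D4 the range was 17.1 to 55.1% over 7 events, and for 293T 15.6 to 24.4% over 4. At D8 the 12 events of the authors' deposited table ranged from 13.6 to 186% with a median of 93.3%. The days do not hold the same events, so these ranges are not like for like. In the authors' deposited tables, the events held at D0 stood at 19.3, 16.6, 13.6 and 60.3% at D8. At D4 the same events stood at 35.2, 23.9, 24.9 and 27.1% in the authors' deposited table. Before scaling, the highest D8 event of the authors' deposited table held 6451 reads in the second arm against 4220 in the first. A 117-nt QKI exon (hg19 chromosome 6, 163899812 to 163899928) fell in inclusion there from 1.0 to 0.129, with 2186 skipping reads in the second arm and 0 in the first. With the same neighbours, the exon fell from 1.0 to 0.773 in the authors' deposited table for D4. With another upstream neighbour, the authors' deposited tables gave this exon a fall from 0.999 to 0.625 at D0 and from 0.997 to 0.588 at D4, but from only 0.998 to 0.976 at D8 (FDR 0.771).

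**Figure D2:**
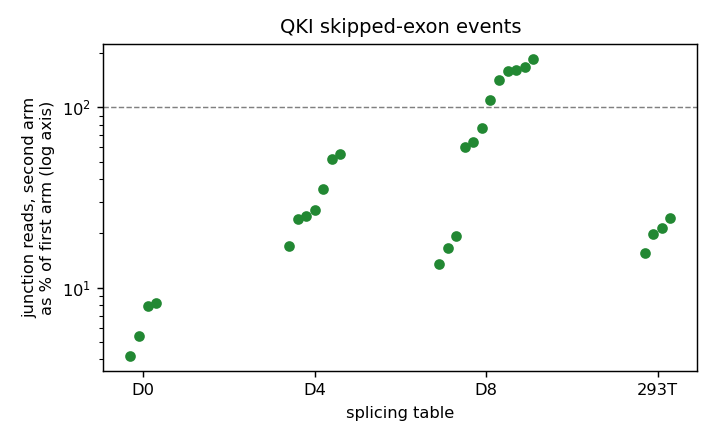
Junction reads of each QKI skipped-exon event with at least 100 reads in an arm, second arm as a percentage of the first (log axis), in the authors' deposited tables. Reads were scaled to the total of each arm, and the dashed line is 100%. Events at D0, D4 and 293T lay between 4.18 and 55.1%, whereas those at D8 spread from 13.6 to 186%. The columns do not hold the same events, so their ranges are not like for like.

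The D0 comparison asked how the KO changed undifferentiated stem cells. Genes of glucose use under low oxygen were lower in KO, and genes of the response to endoplasmic reticulum and amino acid stress higher. Most targets of the tumour suppressor p53 were lower too, but that list was lost (adjusted p = 0.23 with an estimated correlation). LEFTY1 and LEFTY2, secreted inhibitors of NODAL, and CER1, an inhibitor of NODAL and BMP, were higher. Their list, primitive streak, was lost with an estimated correlation. All its genes together summed to 14.5 ± 0.8 CPM in WT and 24.7 ± 2.9 in KO, so their levels were low. Of 21761 genes tested, edgeR called 9209, of which 4656 were higher and 4553 lower in KO; 1863 changed at least 2-fold (775 higher, 1088 lower). Genes were ranked among those called with at least 10 CPM on average and no overlap between the genotypes. The largest rises among the ranked genes were ZNF560 (3.17), ZNF37A (3.12), the histone gene HIST1H2BJ (3), the protocadherin PCDHB5 (2.76) and SYT11, a vesicle protein (2.49). ZNF560 rose from 2.46 ± 0.21 to 22.2 ± 1.4 CPM (SE 0.13, edgeR adjusted p 1.9e-13). HIST1H2BJ and PCDHB5 have near-identical relatives, so their reads are uncertain. The largest falls among the ranked genes were the pseudogene SLC25A3P1 (-4.93, near-identical to its parent), OCIAD2 (-4.27), PKIB, an inhibitor of protein kinase A (-3.82), ARMCX1 (-3.25) and QKI. OCIAD2 fell from 47.5 ± 8.1 to 2.45 ± 0.25 CPM (SE 0.12, edgeR adjusted p 2e-16) and ARMCX1 from 38.2 ± 0.3 to 4 ± 0.15.

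Camera called 6 of the 25 lists at D0, of which 2 held with an estimated correlation. In hypoxia and glycolysis, 11 of 15 genes were lower, 1 higher and 3 not called (12 adjusted over the list alone), with PFKFB4 at -1.78, PDK1 at -1.37 and PGK1 at -1.21. Its camera adjusted p was 6.9e-10, and adjusted p = 0.041 with an estimated correlation. In endoplasmic reticulum and amino acid stress, 10 of 14 were higher, 0 lower and 4 not called (10 adjusted over the list alone), led by SESN2 (1.07), HERPUD1 (1.19) and CHAC1 (1.65). Its camera adjusted p was 7.2e-09, and adjusted p = 0.041 with an estimated correlation. The p53 response had 11 of 17 lower, 2 higher and 4 not called (14 adjusted over the list alone), including BTG2 (-1.50), ZMAT3 (-0.96) and SESN1 (-0.74); camera gave 0.00022, and adjusted p = 0.23 with an estimated correlation. Muscle and cytoskeletal splicing had 21 of 54 higher, 8 lower and 25 not called (32 adjusted over the list alone), with TRDN at 1.92, TTN at 1.59 and TPM1 at 0.98; camera gave 0.0096, and adjusted p = 0.9 with an estimated correlation. Of the U4/U6.U5 tri-snRNP proteins, the splicing particle named in the study's title, 9 of 23 were higher, 1 lower and 13 not called (10 adjusted over the list alone), with DDX23 at 0.55 and SART1 at 0.57; camera gave 0.013, and adjusted p = 0.9 with an estimated correlation. Primitive streak genes had 6 of 14 higher, 1 lower and 7 not called (7 adjusted over the list alone), with LEFTY1 at 3.64, LEFTY2 at 2.30 and CER1 at 2.34; camera gave 0.049, and adjusted p = 0.73 with an estimated correlation.

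Pluripotency genes did not pass at D0 (camera adjusted p 0.085) although 9 of 15 were higher, 1 lower and 5 not called (10 adjusted over the list alone). ZFP42, also known as REX1, fell by 1.93 on the log2 scale while the methyltransferase DNMT3B rose by 1.03. Other uncalled lists held large single changes, such as the angiopoietin receptor TEK (2.12), the BMP target ID1 (1.45) and the WNT feedback ligase RNF43 (-1.28); the splicing repressor PTBP1 moved by 0.45. Median, mean and camera direction differed in sign at D0 for calcium handling (0.00, 0.04, down), presomitic mesoderm (0.18, 0.11, down) and WNT response (0.10, 0.04, down), none of them called.

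The D4 comparison asked how the KO changed cells at the cardiac progenitor stage. Endoderm genes, including the apolipoproteins APOA1 and APOA2, and endothelial genes such as PLVAP, CDH5 and the VEGF receptor KDR were higher in KO. TFAP2A and TFAP2C, transcription factors of surface ectoderm, were lower. Most cell cycle and mitochondrially encoded genes were lower too, but both lists were lost (adjusted p = 0.31 and adjusted p = 0.32 with an estimated correlation). Of 21761 genes, edgeR called 6171, 3556 higher and 2615 lower in KO, with 1235 at 2-fold or more (870 higher, 365 lower). With total counts in place of TMM, 73.8% of called genes were higher, against 57.6%. Ranked genes were again those called with at least 10 CPM on average and no overlap. Their largest rises were FMOD, a collagen-binding proteoglycan (2.49), CD34, a surface protein of blood vessel progenitors (2.44), S100A14 (2.38), the ion channel TRPA1 (2.34) and PCDHB5 (2.33). CD34 rose from 9.19 ± 0.49 to 49.9 ± 4.3 CPM (SE 0.14, edgeR adjusted p 5.1e-11). The largest falls among the ranked genes were NNAT, an imprinted gene (-2.38), TFAP2A (-2.33), CHCHD2, a mitochondrial protein (-2.25), TRIM22 (-2.19) and TFAP2C (-1.97). CHCHD2 fell from 110 ± 11 to 23 ± 0.74 CPM (SE 0.13, edgeR adjusted p 1.2e-10).

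Camera called 13 lists at D4, of which endoderm and endothelial held with an estimated correlation. Endoderm had 13 of 16 genes higher, 0 lower and 3 not called (13 adjusted over the list alone), with APOA2 at 2.28 and APOA1 at 1.74; camera gave 2.2e-17, and adjusted p = 0.015 with an estimated correlation. Its summed level was 226 ± 4.5 CPM in WT and 554 ± 32 in KO. Endothelial genes had 10 of 15 higher, 0 lower and 5 not called (11 adjusted over the list alone), with PLVAP at 3.42, CDH5 at 2.67 and KDR at 0.99; camera gave 2.7e-10, and adjusted p = 0.019 with an estimated correlation. Proliferation had 13 of 15 lower, 0 higher and 2 not called (13 adjusted over the list alone), including AURKB (-0.52), CCNB1 (-0.38) and BUB1 (-0.46), with a median of -0.38 (camera 1.4e-07, adjusted p = 0.31 with an estimated correlation). Mitochondrially encoded genes had 11 of 13 lower, 0 higher and 2 not called (13 adjusted over the list alone), with MT-CO3 at -0.78 and MT-CYB at -0.89 (camera 1.8e-07, adjusted p = 0.32 with an estimated correlation). Genes of the mitochondrial genome took 17.3% ± 1.7 of WT counts and 11.4% ± 0.87 of KO counts.

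The other 9 called lists at D4 were lost with an estimated correlation, and 5 of them belong to development. Pluripotency had 7 of 15 lower, 2 higher and 6 not called (10 adjusted over the list alone), with SOX2 at -1.25 and PRDM14 at -1.40 (camera 0.00054, adjusted p = 0.32 with an estimated correlation). Primitive streak had 9 of 14 higher, 1 lower and 4 not called (10 adjusted over the list alone), with CER1 at 2.28 and GSC at 2.76 (0.00054, adjusted p = 0.26 with an estimated correlation). Cardiac progenitor had 10 of 18 higher, 1 lower and 7 not called (12 adjusted over the list alone), with TBX3 at 1.15 and GATA4 at 0.85 (0.00054, adjusted p = 0.32 with an estimated correlation). Calcium handling had 13 of 23 higher, 1 lower and 9 not called (14 adjusted over the list alone), with TRDN, a protein of the calcium release complex, at 1.41 and the gap junction gene GJA5 at 1.11 (0.0015, adjusted p = 0.34 with an estimated correlation). Surface ectoderm and amnion had 5 of 12 lower, 1 higher (GATA3, 0.98) and 6 not called (6 adjusted over the list alone; 0.0056, adjusted p = 0.41 with an estimated correlation).

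The remaining 4 concern matrix, stress and splicing. Extracellular matrix had 13 of 19 higher, 3 lower and 3 not called (17 adjusted over the list alone), with SPARC at 0.49 and COL4A1 at 0.77 (camera 0.0013, adjusted p = 0.34 with an estimated correlation). Endoplasmic reticulum and amino acid stress had 7 of 14 higher, 1 lower and 6 not called (9 adjusted over the list alone), with XBP1 at 0.97 and HERPUD1 at 0.67 (0.0017, adjusted p = 0.31 with an estimated correlation). The p53 response had 10 of 17 lower, 2 higher and 5 not called (12 adjusted over the list alone), with MDM2 at -0.43 and PHLDA3 at -0.71 (0.0038, adjusted p = 0.32 with an estimated correlation). U4/U6.U5 tri-snRNP proteins had 5 of 23 lower, 0 higher and 18 not called (4 adjusted over the list alone), with EFTUD2 at -0.22 and PRPF8 at -0.24 (0.0046, adjusted p = 0.41 with an estimated correlation). Among lists not called at D4, sarcomere genes had 7 of 30 higher, 3 lower and 20 not called. Median, mean and camera direction differed in sign for presomitic mesoderm (-0.15, -0.12, up), smooth muscle (0.06, 0.30, down) and muscle and cytoskeletal splicing (-0.02, 0.04, down).

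The D8 comparison asked how cardiomyocytes differed. In the libraries labelled KO, genes of the contractile apparatus, calcium handling and energy supply were mostly higher, while genes of surface ectoderm and amnion, cell division and pluripotency were mostly lower. None of these 6 lists held with an estimated correlation (adjusted p = 0.08 for surface ectoderm and amnion, and from 0.13 to 0.37 for the others). ACTN2, which anchors the sarcomere's thin filaments, KCNJ2, a potassium channel, and LPL, a lipase, went against their lists and fell. Of 21761 genes, edgeR called 12097, 6396 higher and 5701 lower in the libraries labelled KO, with 3617 at 2-fold or more (1404 higher, 2213 lower). With total counts, 37.6% of called genes were higher, against 52.9%, and the median of all genes moved from 0.006 to -0.122.

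At D8, too, genes were ranked among those called with at least 10 CPM on average and no overlap. The largest rises among the ranked genes were the collagen COL3A1 (4.88), the hormone precursor TRH (3.43), the growth factors BMP5 (3.13) and WNT2 (2.98), and FITM1, a lipid droplet protein (2.86). COL3A1 was at 11.3 ± 2.6 CPM in WT and 334 ± 43 in the libraries labelled KO (SE 0.36, edgeR adjusted p 4.5e-10). BMP5 was at 22.7 ± 1.2 and 199 ± 16 CPM (SE 0.11, edgeR adjusted p 1.1e-14). Without D8_WT replicate 2, the value for WNT2, KO against WT at D8, was 3.59. ZNF558, a zinc finger gene, held 8834 counts in WT and 2 in the libraries labelled KO, a ratio of 3330 (95% counting interval 921 to 27500). TFAP2A fell from 173 ± 37 to 1.46 ± 0.52 CPM (-6.89, edgeR adjusted p 4.4e-14). The transcription factor DLX5 (-6.71), the imprinted noncoding RNA MEG3 (-6.60) and the GABA receptor subunit GABRP (-6.54) complete the largest falls among the ranked genes. Genes under the 10 CPM limit fell further, among them NNAT (at least 1030-fold, against the floor). MEG3 fell from 133 ± 24 to 1.37 ± 0.39 CPM. In D8 nuclear RNA these changes were smaller or absent. COL3A1 (0.57) and WNT2 (-0.53) did not pass there, while TRH (1.39), BMP5 (2.39) and FITM1 (1.21) were higher. TFAP2A (-1.05), DLX5 (-1.04), MEG3 (-1.19) and GABRP (-1.71) were lower, and ZNF558 (-0.01) and NNAT (-0.56) did not pass. COL3A1 stood at 801.1 to 1455 CPM in nuclear WT and 1068 to 2535 in the nuclear libraries labelled KO.

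Camera called 13 lists at D8, none of which held with an estimated correlation, where 0 were called. Surface ectoderm and amnion had 11 of 12 genes lower, 0 higher and 1 not called (11 adjusted over the list alone), with TFAP2A, TFAP2C (-4.16) and TP63 (-3.10), and a median of -5.07 (camera 3.4e-17, adjusted p = 0.08 with an estimated correlation). Its summed level was 1070 ± 310 CPM in WT and 91.8 ± 10 in the libraries labelled KO. All 15 proliferation genes were lower (15 adjusted over the list alone), including CCNB2 (-1.09), CDC20 (-1.10) and AURKB (-0.99) (camera 1.2e-14, adjusted p = 0.13 with an estimated correlation). Pluripotency had 11 of 15 lower, 1 higher and 3 not called (13 adjusted over the list alone), with POU5F1 at -4.25, L1TD1 at -3.74 and LIN28A at -1.43 (1e-07, adjusted p = 0.24 with an estimated correlation). Its summed level was 9170 CPM in D0 WT, 1770 ± 240 in D8 WT and 708 ± 59 in the D8 libraries labelled KO.

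Sarcomere genes had 22 of 30 higher, 3 lower and 5 not called at D8 (25 adjusted over the list alone), with MYBPC3 at 1.49, TNNC1 at 1.37 and ACTN2 at -2.07 (camera 5.7e-05, adjusted p = 0.37 with an estimated correlation). Their summed level was 25300 ± 5500 CPM in WT and 48900 ± 3700 in the libraries labelled KO. Cardiac progenitor had 13 of 18 higher, 1 lower and 4 not called (14 adjusted over the list alone), with IRX4 at 2.52, GATA4 at 1.60 and GATA5 at 1.29 (5.7e-05, adjusted p = 0.29 with an estimated correlation). Calcium handling had 17 of 23 higher, 3 lower and 3 not called (20 adjusted over the list alone), with PLN at 2.33, HCN4 at 1.85 and KCNJ2 at -5.20 (5.7e-05, adjusted p = 0.29 with an estimated correlation). Energy metabolism had 16 of 18 higher, 1 lower and 1 not called (17 adjusted over the list alone), with PPARGC1A at 1.59, CKM at 1.41 and LPL at -3.20 (0.00019, adjusted p = 0.29 with an estimated correlation). Muscle and cytoskeletal splicing had 32 of 54 higher, 10 lower and 12 not called (44 adjusted over the list alone), with PDLIM5 at 1.35, CACNA1C at 1.28 and ENAH at -1.34 (0.00061, adjusted p = 0.37 with an estimated correlation).

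The other 5 lists called at D8 had medians from 0.09 to 0.51. Endothelial genes had 10 of 15 higher, 1 lower and 4 not called (12 adjusted over the list alone), with KDR at 1.47 and CLDN5 at 1.91 (camera 0.0082, adjusted p = 0.29 with an estimated correlation). Endoderm had 10 of 16 higher, 1 lower and 5 not called (13 adjusted over the list alone), with APOA1 at 1.14 and FOXA2 at 0.81 (0.026, adjusted p = 0.4 with an estimated correlation). The p53 response had 10 of 17 higher, 2 lower and 5 not called (12 adjusted over the list alone), with FDXR at 0.95 and CDKN1A at 0.89 (0.026, adjusted p = 0.37 with an estimated correlation). Extracellular matrix had 9 of 19 higher, 6 lower and 4 not called (15 adjusted over the list alone), with COL6A3 at 2.33 and COL6A2 at 1.28 (0.026, adjusted p = 0.44 with an estimated correlation). Mitochondrially encoded genes had 12 of 13 higher, 0 lower and 1 not called (12 adjusted over the list alone), with MT-ND3 at 0.59 and MT-ND5 at 0.65 (0.042, adjusted p = 0.56 with an estimated correlation).

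Lists not called at D8 went both ways. Epicardium genes had 3 of 12 higher, 5 lower and 4 not called (8 adjusted over the list alone; camera 0.059), with BNC1 at -3.04 and BNC2 at -3.19. WNT response had 8 of 13 higher, 4 lower and 1 not called (13 adjusted over the list alone; 0.11), with AXIN2 at 0.91 and MSX1 at -2.23. BMP and TGF-beta response had 4 of 14 higher, 6 lower and 4 not called (10 adjusted over the list alone; 0.72), with TGFBI at -3.22 and SMAD6 at 0.88. Neural genes had 5 of 11 higher, 3 lower and 3 not called (8 adjusted over the list alone; 0.76), with LHX2 at 4.21 and DCX at -1.35. Among splicing factors, the U1 snRNP list had 7 of 11 lower, 1 higher and 3 not called (0.11), with SNRPA at -0.41, and the muscle and tissue splicing regulators had 9 of 22 higher, 8 lower and 5 not called (0.5), with RBFOX2 at 0.87 and ESRP1 at -1.38. U4/U6.U5 tri-snRNP proteins had 5 of 23 higher, 6 lower and 12 not called (11 adjusted over the list alone; 0.82), with PRPF3 at -0.52, and their median of 0.02 differed in sign from the mean of -0.02 and the camera direction.

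**Figure D3:**
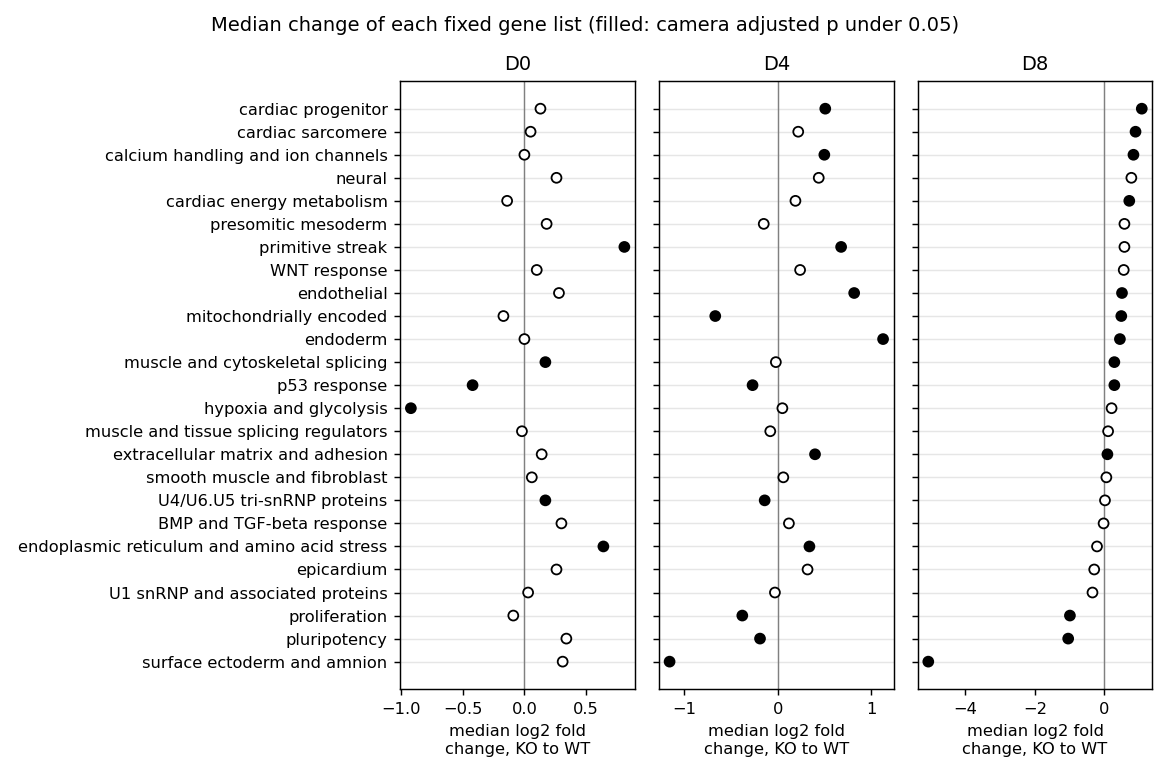
Median log2 fold change, KO to WT, of the tested members of each of the 25 gene lists at D0, D4 and D8; filled points have a camera adjusted p under 0.05. Surface ectoderm and amnion fell to -5.07 at D8, while sarcomere genes stood at 0.05 at D0, 0.22 at D4 and 0.90 at D8.

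The nuclear comparison asked which of the D8 differences were present in RNA of the nucleus. Genes of the sarcomere and of calcium handling were higher in the libraries labelled KO, as was KDR, and cell cycle genes were lower. These 3 lists were lost (adjusted p = 0.19 with an estimated correlation in each). Endoderm genes such as AFP and SERPINA1, which encode secreted liver proteins, were also higher (list adjusted p = 0.22 with an estimated correlation). Nuclear WT replicates 2 and 3 differed by little more than counting error (reduced chi-square 1.22), so the nuclear SDs and p-values with n = 3 rest on the unstated assumption that they are separate cultures. Of 30481 genes tested, edgeR called 19515, 9508 higher and 10007 lower in the libraries labelled KO, with 7505 at 2-fold or more (3037 higher, 4468 lower). The median of all genes lay at -0.271, and at -0.721 with total counts. With total counts 25.6% of called genes were higher, against 48.7%, and with the DESeq2 Wald test 67.8%.

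Most of the lower genes were ones barely seen in whole cells. Among 15516 genes with under 1 CPM in the D8 whole-cell libraries or not listed there, 8156 were lower and 535 higher, with a median of -0.76. Among the other 14965 genes, refitted alone, 9136 were called, 4483 higher and 4653 lower, and the median was -0.019. QKI then stood at 1.12 (edgeR adjusted p 1.9e-06). This alternative was chosen after the data were seen. Olfactory receptor genes, whose known role is in smell, had a count in at least 98.4% of the 374 genes in every nuclear library, against at most 36.6% of 134 in D8 whole-cell libraries. Their summed level was 662 ± 110 CPM (over plain total counts) in nuclear WT and 271 ± 90 in the nuclear libraries labelled KO.

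**Figure D4:**
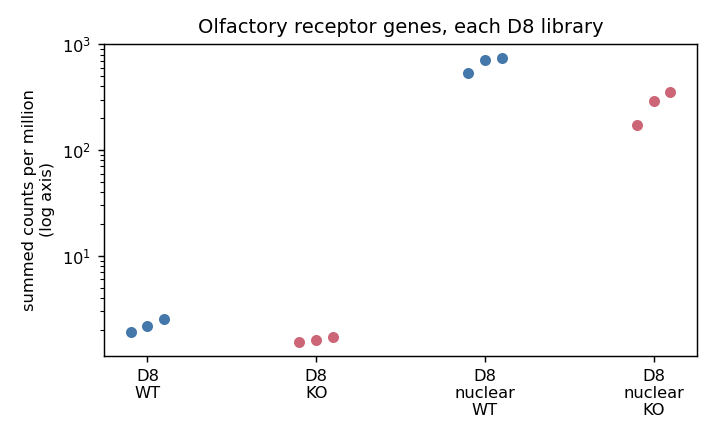
Summed CPM of olfactory receptor genes (log axis) in each D8 library, WT in blue and libraries labelled KO in red. Nuclear libraries held means of 662 (WT) and 271 (KO), and the 6 whole-cell libraries between 1.54 and 2.51.

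Among called genes with at least 10 CPM on average and no overlap, the largest nuclear rises were SPINK1 (5.02), AFP (4.79), KDR (3.86), PRSS42 (3.76) and HKDC1 (3.69). KDR rose from 30.7 ± 6.7 to 447 ± 26 CPM (SE 0.18, edgeR adjusted p 3.8e-17), and AFP from 8.07 ± 1.7 to 224 ± 130. Nuclear KO replicate 2 stood apart: AFP was at 375.5 CPM there against 155.9 and 141.1 in the other KO libraries, SPINK1 at 129.9 against 59.9 and 51.97, and HKDC1 at 183.4 against 73.81 and 74.18. Without D8_nuclear_KO replicate 2 the log2 fold change was 4.20 for AFP, KO against WT in D8 nuclear RNA, 4.49 for SPINK1, KO against WT in D8 nuclear RNA, and 3.11 for HKDC1, KO against WT in D8 nuclear RNA. In whole cells at D8, KDR was higher too (1.47), and PRSS42 (-0.06) and HKDC1 (-0.14) did not pass. SPINK1 (-0.56) and AFP (-0.63) were called lower there, on weak grounds. SPINK1 was low, at 0.4992, 0.5452 and 0.5829 CPM in WT and 0.3709, 0.3742 and 0.3546 in the libraries labelled KO. AFP stood at 16.22, 54.91 and 58.04 CPM in WT and 30.39, 28.47 and 24.51 in the libraries labelled KO. Its groups thus overlapped (edgeR adjusted p 0.046). With the same limits, the largest nuclear falls were RN7SL471P (-8.35), HIST1H3C (-6.71), CHCHD2 (-3.85), HIST1H4I (-2.93) and HIST1H3G (-2.83). The 7SL pseudogene and the histone genes have near-identical copies and are uncertain. Histone genes took 0.3305% of counts in nuclear WT and 0.1404% in nuclear KO, and 7SL genes 0.06473% and 0.03286%. CHCHD2 fell from 34.8 ± 2.8 to 2.44 ± 0.64 CPM in nuclear RNA (SE 0.18, edgeR adjusted p 2.2e-17). In whole cells it was lower in the libraries labelled KO at all 3 days (-0.59 at D0, -2.25 at D4 and -6.03 at D8).

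Camera called 18 lists in nuclear RNA, and 0 with an estimated correlation. It compares each list with the other tested genes, here including the 15516 barely seen in whole cells, whose median was -0.76. A list of expressed genes can rank as higher for that reason alone, and camera was not rerun without those genes. Sarcomere genes had 27 of 30 higher, 2 lower and 1 not called (29 adjusted over the list alone), with XIRP1 at 2.52 and NEXN at 2.11 (camera 1.1e-22, adjusted p = 0.19 with an estimated correlation); in the refit 21 of 29 were higher and 2 lower. Muscle and cytoskeletal splicing had 48 of 54 higher, 0 lower and 6 not called (48 adjusted over the list alone), with MEF2A at 2.07 and LDB3 at 2.29 (1.1e-22, adjusted p = 0.19 with an estimated correlation), and 36 higher and 3 lower in the refit. Calcium handling had 17 of 23 higher, 3 lower and 3 not called (20 adjusted over the list alone), with HCN4 at 2.32 and GJA1 at 2.26 (9.6e-11, adjusted p = 0.19 with an estimated correlation). Proliferation had 14 of 15 lower, 0 higher and 1 not called (14 adjusted over the list alone), with TOP2A at -1.50 and MKI67 at -1.32 (9.6e-11, adjusted p = 0.19 with an estimated correlation). Endoderm had 12 of 16 higher, 2 lower and 2 not called (14 adjusted over the list alone), with SERPINA1 at 3.49 (4.2e-08, adjusted p = 0.22 with an estimated correlation); its summed level was 90.9 ± 4.9 CPM in WT and 602 ± 290 in the libraries labelled KO. Surface ectoderm and amnion had 10 of 12 lower, 0 higher and 2 not called (10 adjusted over the list alone), with WNT6 at -1.49 and TFAP2A at -1.05 (0.00041, adjusted p = 0.19 with an estimated correlation). The median of this list, -0.95, was close to that of olfactory receptor genes in the same fit (-0.93). Its nuclear fall is thus not told apart from the general fall of genes barely seen in whole cells.

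Some nuclear list results changed when the genes barely seen in whole cells were left out. Of the U4/U6.U5 tri-snRNP proteins 17 of 23 were higher, 0 lower and 6 not called (17 adjusted over the list alone), with PRPF8 at 1.13 (camera 0.0011, adjusted p = 0.44 with an estimated correlation), but in the refit 6 were higher and 6 lower. Endoplasmic reticulum and amino acid stress had 4 of 14 higher and 10 not called in the whole fit (3 adjusted over the list alone; camera 0.57), and 0 higher and 7 lower in the refit. The p53 response had 15 of 17 higher, 0 lower and 2 not called (15 adjusted over the list alone), with CDKN1A at 1.68 (5.8e-06, adjusted p = 0.19 with an estimated correlation), and 8 higher and 0 lower in the refit. Endothelial genes had 11 of 14 lower, 1 higher (KDR) and 2 not called in nuclear RNA (12 adjusted over the list alone, camera 0.078), and 12 lower and 1 higher in the refit. Their median in the whole fit, -0.76, equalled that of the genes barely seen in whole cells (-0.76). The refit does not remove any reads unrelated to expression from the genes it keeps, so it does not separate the 2. The U1 snRNP list had 10 of 11 higher, 0 lower and 1 not called (10 adjusted over the list alone), with LUC7L at 1.42 and TIA1 at 1.16 (5.7e-05, adjusted p = 0.32 with an estimated correlation). For WNT response the median of 0.08 differed in sign from the mean of -0.14 and the camera direction.

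Across 20049 genes of both tables, the nuclear and whole-cell KO effects at D8 correlated at a Pearson r of 0.285, a correlation across genes, which are not independent replicates. Of 8228 genes called in both, 68.4% moved in the same direction. By chance 2901 would have been higher in both, against 3988 found, and 1124 lower in both, against 1637 found.

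The WT comparisons followed the differentiation itself. From D0 to D4 the pluripotency factor NANOG fell and TBX3, GATA4 and PDGFRA, genes of cardiac progenitors, rose along with the endoderm factors FOXA2 and SOX17. edgeR called 17636 genes, 9130 higher and 8506 lower at D4, with 10498 at 2-fold or more; total counts moved the median of all genes from 0.075 to 0.192. Pluripotency had 13 of 15 lower, 1 higher and 1 not called (14 adjusted over the list alone), with NANOG at -6.08 and DPPA2 at -4.19 (camera 2e-07, adjusted p = 0.11 with an estimated correlation). Cardiac progenitor had 17 of 18 higher, 1 lower and 0 not called (18 adjusted over the list alone), with TBX3 at 8.89 and GATA4 at 7.73 (2.3e-15, adjusted p = 0.062 with an estimated correlation). SOX17 was at least 1580-fold higher and the presomitic gene RIPPLY1 at least 561-fold higher, against the floor over the D0 group. Presomitic mesoderm had 8 of 11 higher, 1 lower and 2 not called (9 adjusted over the list alone), with FOXC2 at 7.65 (0.024, adjusted p = 0.13 with an estimated correlation). Camera called 15 lists, and only BMP and TGF-beta response, with 11 of 14 higher, 2 lower and 1 not called (13 adjusted over the list alone; ID1 5.46, ID4 4.90), held with an estimated correlation (6e-08, adjusted p = 0.016 with an estimated correlation). Median and mean were positive but camera pointed down for calcium handling (0.12, 0.38) and endothelial genes (0.46, 0.48), neither called.

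From D4 to D8 in WT, genes of the contractile apparatus such as LDB3, MYBPC3 and ACTN2 rose, and PRDM14 and SOX2, factors of the pluripotent state, fell further. edgeR called 14975 genes, 7624 higher and 7351 lower at D8, with 6310 at 2-fold or more. Camera called 16 lists and 7 held with an estimated correlation. Sarcomere had 29 of 30 higher, 0 lower and 1 not called (29 adjusted over the list alone), with a median of 5.59 and ACTN2 at 7.70 (camera 3.5e-51, adjusted p = 0.026 with an estimated correlation). Endothelial had 12 of 15 higher, 1 lower and 2 not called (13 adjusted over the list alone), with PLVAP at 6.48 (2.9e-09, adjusted p = 0.028 with an estimated correlation). Pluripotency, calcium handling, energy metabolism, presomitic mesoderm and BMP and TGF-beta response were the other lists that held. Cardiac progenitor had 15 of 18 higher, 3 lower and 0 not called (18 adjusted over the list alone), with NKX2-5 at 6.79 and MEF2C at 5.95 (6.1e-07, adjusted p = 0.085 with an estimated correlation). In surface ectoderm and amnion 12 of 12 were higher (12 adjusted over the list alone), with TP63 at 6.60 and VTCN1 at 6.63 (6.5e-06, adjusted p = 0.11 with an estimated correlation). Smooth muscle and fibroblast had 7 of 16 higher, 6 lower and 3 not called (13 adjusted over the list alone; 0.12), with ACTA2 at 7.06. Muscle and tissue splicing regulators had 11 of 22 higher, 5 lower and 6 not called (16 adjusted over the list alone), with MBNL2 at 3.61 and RBM38 at 1.98 (0.015, adjusted p = 0.086 with an estimated correlation), and the U1 snRNP list had 9 of 11 lower, 1 higher and 1 not called (10 adjusted over the list alone), with LUC7L at -1.18 (0.0077, adjusted p = 0.086 with an estimated correlation). For WNT response, not called, the median of -0.11 and the camera direction differed in sign from the mean of 0.29.

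Interactions asked whether the KO effect changed between days. The labels do not say that the libraries labelled KO come from the same clone at each day and in nuclear RNA, so a difference between days, or between nuclear and whole-cell RNA, is not told apart from one between clones. OCIAD2, PKIB and ARMCX1, lower in D0 KO, were less changed at D4, whereas TFAP2A and MEG3 became lower in the libraries labelled KO mainly between D4 and D8. Most hypoxia and glycolysis genes were less changed at D4, and most surface ectoderm and amnion genes were lower at D8, but both lists were lost (adjusted p = 0.16 and adjusted p = 0.2 with an estimated correlation). From D0 to D4 the KO effect differed for 8518 genes in edgeR, 4352 of them more positive at D4 and 4166 more negative. From D4 to D8 it differed for 9037, 4267 more positive and 4770 more negative. With total counts the more positive share was 62.9%, against 51.1%, for D0 to D4 and 24.9%, against 47.2%, for D4 to D8, and the median of all genes moved to 0.132 and -0.243. Camera called 9 and 11 lists, and 0 in each with an estimated correlation. Hypoxia and glycolysis had 12 of 15 more positive at D4 than at D0, 1 more negative and 2 not called (13 adjusted over the list alone; camera 6.8e-08, adjusted p = 0.16 with an estimated correlation). The surface ectoderm and amnion list had 10 of 12 more negative at D8 than at D4, 0 more positive and 2 not called (10 adjusted over the list alone; 1.5e-08, adjusted p = 0.2 with an estimated correlation). Mitochondrially encoded genes had 12 of 13 more positive at D8, 0 more negative and 1 not called (12 adjusted over the list alone; 1e-07, adjusted p = 0.4 with an estimated correlation). Median, mean and camera direction differed in sign, in lists not called, from D0 to D4 for cardiac progenitor (0.43, 0.25, down), presomitic mesoderm (-0.20, -0.23, up), WNT response (-0.06, 0.32, up), epicardium (-0.34, 0.13, down), smooth muscle (0.15, -0.13, down), neural (0.03, -0.01, down) and muscle and tissue splicing regulators (0.00, 0.05, down). From D4 to D8 they differed for primitive streak (-0.09, -0.26, up), WNT response (0.45, -0.25, up), smooth muscle (0.33, -0.02, up), neural (0.03, -0.04, up) and extracellular matrix (-0.05, 0.05, up).

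Across 21761 genes the KO effects correlated at a Pearson r of 0.115 between D0 and D4, 0.111 between D0 and D8 and 0.286 between D4 and D8, across genes that are not independent replicates. Between D0 and D4 the sign turned by rank (Spearman -0.056) and over 8869 genes at 10 CPM (Pearson -0.06); for D0 and D8 these were 0.094 and 0.086, and for D4 and D8 0.201 and 0.242. Of genes called on both days, 43.5% of 3150 moved in the same direction at D0 and D4, 58.3% of 5473 at D0 and D8, and 68.7% of 4142 at D4 and D8. PCDHB5 was higher in the libraries labelled KO at each day (2.76, 2.33 and 2.05) and in nuclear RNA (1.71), as was ZNF37A (3.12, 2.17, 2.31 and 1.03). FMOD was higher from D4 on (2.49, 2.51 and, in nuclear RNA, 3); its nuclear KO libraries stood at 24.38, 60.35 and 20.21 CPM, with replicate 2 apart. ZNF560 was higher at D0 (3.17) and D4 (1.49) and lower at D8 (-0.67), and SYT11 likewise (2.49, 0.99 and -0.94). The D8 levels of ZNF560 were low, at 0.2557 to 0.393 CPM in WT and 0.152 to 0.2318 in the libraries labelled KO. ZNF558 was lower at D0 (-1.16) and D4 (-1.10) but not in nuclear RNA (-0.01).

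Splicing was compared to find exons whose use depends on QKI, the subject of the study's title. A 129-nt exon of LPHN2, an adhesion receptor, was nearly absent in the first arm and nearly always included in the second arm of all 4 of the authors' deposited tables. Exons of SYNRG, which acts in vesicle traffic, of RALGAPA1, a GTPase activator, and of the centrosome protein NIN went the other way. Among the largest changes at D8 were single exons of RYR2, the calcium release channel, SLC8A1, the sodium-calcium exchanger, and CACNA1C, a calcium channel of the cell membrane. The tables name no arm. Across genes, the log ratio of junction reads (second to first arm) in the authors' deposited tables correlated with the KO to WT fold change of the same day at 0.89 for D0, 0.92 for D4 and 0.956 for D8, and at 0.277 or less with other days. For 293T no such test was possible, and its ratios correlated with none of the days (0.024, -0.049 and 0.014). Its second arm held 15.6 to 24.4% of the QKI junction reads of the first, over 4 events of the authors' deposited table. All 62 events called in both 293T and D4 had the same sign. These values argue against the second arm of 293T being the control siRNA.

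At D0, 1867 of 78672 events with enough reads were called in the authors' deposited table, with inclusion higher in the second arm for 834 and lower for 1033, in 1341 genes; limma on the inclusion levels of the authors' deposited table called 213. The largest rises in the authors' deposited table were exons of VPS29 (0.05 to 0.975), LPHN2 (0.078 to 0.981), FSD1L (0.0 to 0.733), AFAP1 (0.101 to 0.803) and DENND4C (0.293 to 0.994). AKAP9, which anchors protein kinase A, fell from 1.0 to 0.044 in the authors' deposited table, and SYNRG from 0.934 to 0.04, SYTL2 from 0.864 to 0.048, RALGAPA1 from 1.0 to 0.228 and MYO18A from 0.864 to 0.114. In the muscle and cytoskeletal list the authors' deposited table gave ANK3 (-0.598), DST (-0.594) and CLASP1 (0.597).

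At D4, 647 of 58983 events were called in the authors' deposited table, 329 higher and 318 lower in the second arm, in 493 genes, and 74 by limma on its inclusion levels. LPHN2 rose from 0.041 to 0.972 in the authors' deposited table, followed by COL25A1 (0.782), AFAP1 (0.636), CLASP1 (0.626) and the kinase MAP4K4 (0.607). RALGAPA1 fell from 0.987 to 0.078, NIN from 0.967 to 0.059, SYNRG from 0.897 to 0.017 and MYO18A from 0.872 to 0.054 in the authors' deposited table. NUMB, a regulator of NOTCH signalling (-0.632), MACF1 (0.505) and ANK3 (-0.457) changed in the same list and the authors' deposited table.

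At D8, 1768 of 79117 events were called in the authors' deposited table, 958 higher and 810 lower in the second arm, in 1154 genes, and 390 by limma on its inclusion levels. The authors' deposited table put LPHN2 at 0.034 and 0.937, the potassium channel KCNH7 at 0.099 and 0.957, AFTPH at 0.044 and 0.885, and AFAP1 at 0.113 and 0.945. A pair of neighbouring 60-nt CACNA1C exons exchanged in the authors' deposited table: that at 2706603 to 2706662 of chromosome 12 rose from 0.056 to 0.902 and that at 2706396 to 2706455 fell from 0.817 to 0.072. A 36-nt RYR2 exon (chromosome 1, 237889573 to 237889608) fell from 0.994 to 0.002, and a 15-nt SLC8A1 exon (chromosome 2, 40401846 to 40401860) from 0.977 to 0.001, in the authors' deposited table. AKAP9 fell from 1.0 to 0.0, SYNRG from 0.99 to 0.034 and NIN from 0.987 to 0.033 in the authors' deposited table. MEF2D, a muscle transcription factor, rose from 0.074 to 0.845, SORBS2 rose from 0.251 to 0.924 and PDLIM5 fell from 0.994 to 0.315 in the authors' deposited table.

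In 293T, 203 of 45021 events were called in the authors' deposited table, 124 higher and 79 lower in the second arm, in 160 genes, and 50 by limma on its inclusion levels (up to 25 in other splits of the libraries). The authors' deposited table gave rises for LPHN2 (0.06 to 0.874), the translation factor EEF1D (0.035 to 0.694), DEPDC1 (0.387 to 0.978), ESYT2 (0.416 to 0.862) and PHF21B (0.0 to 0.437). SLMAP, a membrane protein of muscle and other cells, fell from 0.961 to 0.141, RALGAPA1 from 0.928 to 0.261, SYNRG from 0.77 to 0.103 and SEC16A from 0.697 to 0.123 in the authors' deposited table. DST (-0.544), FN1 (0.404), SPTAN1 (0.36), BIN1 (0.304) and EXOC1 (0.281) changed among the muscle and cytoskeletal list in the authors' deposited table.

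Counted per event and sign, 3372 were called in 1 of the authors' deposited tables, 280 in 2, 127 in 3 and 43 in all 4. An event called with opposite signs in different tables counts once under each sign. Among those in all 4 were exons of LPHN2, SYNRG, RALGAPA1, NIN, AFAP1, SLMAP and MYO18A. Fisher's exact tests found more shared events than chance for each pair of the authors' deposited tables. D4 and D8 shared 275 events against 16.9 expected (odds ratio 36.5, adjusted p 3.8e-264), 94.5% with the same sign. D4 and 293T shared 62 against 2.05 expected (odds ratio 54.4, adjusted p 1e-74), all 62 with the same sign. For D8 and 293T it was 70 against 4.65 expected (98.6%), for D0 and 293T 69 against 5.11 (89.9%), for D0 and D4 214 against 17.0 (89.7%) and for D0 and D8 321 against 38.8 (85.4%).

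**Figure D5:**
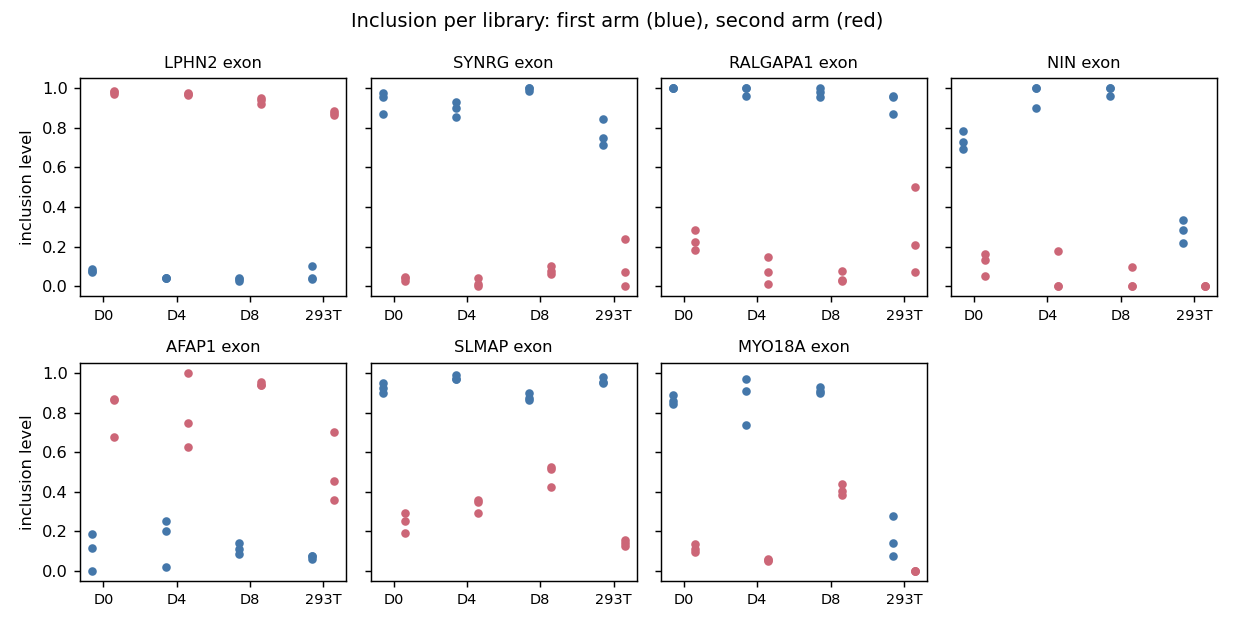
Inclusion level per library in the authors' deposited tables, first arm (blue) and second arm (red), 3 libraries each, for 7 exons called with the same sign in all 4 tables. LPHN2 rose from 0.078 to 0.981 at D0 and from 0.06 to 0.874 in 293T, whereas MYO18A fell from 0.864 to 0.114 at D0 and from 0.164 to 0.0 in 293T.

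Genes of the muscle and cytoskeletal splicing list, such as RYR2, CACNA1C, MEF2D and PDLIM5, held called events more often than other genes in each of the authors' deposited tables. At D8, 41 of 54 list genes (75.9%) had a called event against 9.42% of others (odds ratio 30.3, Fisher's exact adjusted p 2e-30). At D0 the authors' deposited table gave 19 of 47 (40.4%) against 11.3% (odds ratio 5.31, adjusted p 3.4e-07), at D4 19 of 49 (38.8%) against 4.35% (13.9, 2e-13) and in 293T 12 of 42 (28.6%) against 1.63% (24.1, 5.5e-12). The list was drawn from genes whose splicing is known to be regulated, and its genes often have many annotated exons, which was not corrected for. Genes with a called event were not more often called in expression: Fisher's exact odds ratios were 1.02 at D0, 1.11 at D4 and 1.07 at D8 (p 0.77, 0.27 and 0.29; 0.94, 0.82 and 0.82 adjusted over 12 tests).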

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

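The 4 tests on QKI, the scaling test of the amnion genes and the depth test of the nuclear libraries were chosen after the result was seen; all others were set out before. The results in this and the next paragraph stand here because the KO effect differed between days by an edgeR interaction test; the 3 patterns after them are weighed because a reader would want to follow them up. From D0 to D4 the effect differed for 8518 genes and 9 lists, and from D4 to D8 for 9037 genes and 11 lists; 0 of these lists held with an estimated correlation. Of 50 splits of the libraries, the real one included, 1 gave at least as many genes for D0 to D4 (highest other 4461). For D4 to D8 it was 2 (highest other 10292). Splits that mixed the genotypes on both days gave 0 genes, since mixing adds the KO to WT difference to the spread. They do not show what equal KO effects on both days would give, so they leave chance open for the gene counts. The split with 10292 kept D4 as it was and exchanged KO and WT at D8, which tests the sum of the effects and not their difference. For lists, 11 of the 50 splits reached the real count for D0 to D4 (highest other 14) and 20 for D4 to D8 (highest other 15), so chance was not excluded for the list counts.

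The KO effect on QKI rose by 1.99 from D0 to D4 and by 0.95 from D4 to D8. From D0 to D4 the log2 effect became more positive for SLC25A3P1 (1.69), OCIAD2 (3.49), PKIB (2.49), ARMCX1 (2.87), FMOD (1.94), CD34 (2.55), S100A14 (2.93), TRPA1 (2.34) and NNAT (1.10). It became more negative for ZNF560 (-1.69), ZNF37A (-0.96), HIST1H2BJ (-2.73), PCDHB5 (-0.44), SYT11 (-1.50), CHCHD2 (-1.66), TRIM22 (-1.27), TFAP2C (-1.47) and MEG3 (-1.73). From D4 to D8 it became more positive for OCIAD2 (0.89), ARMCX1 (0.66), COL3A1 (3.31), TRH (3.26), BMP5 (1.74) and FITM1 (2.71). It became more negative for ZNF560 (-2.15), SYT11 (-1.93), PKIB (-2.10), CD34 (-2.25), S100A14 (-3.25), TRPA1 (-3.42), TFAP2A (-4.56), TFAP2C (-2.19), CHCHD2 (-3.78), DLX5 (-2.78), MEG3 (-6.83) and GABRP (-5.25). Single D4 libraries weigh on 3 of these: COL3A1 stood at 46.35, 18.01 and 9.573 CPM in D4 KO, and in D4 WT GABRP at 5.626, 1.497 and 1.439 and DLX5 at 4.951, 1.497 and 2.183. Low levels weigh on more of them. Every library of a day was under 1 CPM for ZNF560 and TRPA1 at D8, FITM1 and HIST1H2BJ at D4, and FMOD and CD34 at D0. So was SLC25A3P1 in D4 KO. Of the genes named here, NNAT (-10.51) and ZNF558 (-10.32) changed most from D4 to D8, but held 0 and 2 counts in the D8 libraries labelled KO, so these 2 values depend on the constant added by the fit. As a bound, NNAT was at least 1030-fold lower at D8, with 4098 counts in WT.

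QKI was not lower in the D8 libraries labelled KO. Scaling does not account for this, since the lowest log2 fold change over the alternatives was -0.08. Nor do swapped D8 labels: in the authors' deposited tables the second arm of D8 followed the whole-cell libraries labelled KO (r 0.956) and 94.5% of events called at both D4 and D8 had the same sign, and nuclear and whole-cell KO effects at D8 correlated at 0.446 over 9619 genes at 10 CPM. An edited allele that keeps most of the transcript is a candidate explanation: in the authors' deposited table for D8 the 3 QKI events that use the exon ending at 163876453 fell to between 13.6 and 19.3% of the first arm, while the others stood at 60.3 to 186%. The loss was not confined to that exon. In the authors' deposited table, 1 of the others, an event of the 117-nt exon, stood at 64.4% mostly through 2186 skipping reads. Its inclusion reads were 641 in the second arm against 5345 in the first. Higher values at downstream exons were not particular to D8. In the authors' deposited table for D4, events of the exons ending at 163987827 stood at 51.5 and 55.1%, and the others at 17.1 to 35.2%. The labels do not give the edit, so the explanation by an edited allele was not tested directly.

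Surface ectoderm and amnion genes were mostly lower in the D8 libraries labelled KO, though the list was lost (adjusted p = 0.08 with an estimated correlation). Scaling does not account for this: at least 11 markers were lower under TMM (median -5.07), DESeq2 factors (-5.05) and total counts (-5.20). A smaller share of epithelial cells is possible but was not settled, as the median of 20 epithelial genes was -0.92, between the limits set beforehand of -1 and -0.5; 15 were lower, such as CDH1 (-1.64) and KRT8 (-0.82), named after their values were seen, and 0 higher. CHIR dose could not be told from genotype, since 0 doses were used for both genotypes at D8.

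Slightly more genes were lower (10007) than higher (9508) in the nuclear libraries labelled KO, but this depends on scaling and filter: 8638 and 10265 with DESeq2 factors, 15074 and 5192 with total counts, and 7803 and 10294 without the low-count filter. Reads unrelated to expression may be one reason for the lower genes. The summed CPM of olfactory receptor genes was 2.44 times as high in nuclear WT as in KO, and of 276 olfactory genes tested 152 were lower and 0 higher, with a median of -0.93. Deeper WT libraries do not account for it, since the shallowest KO library held 1.11 times the counts of the deepest WT library. No biological explanation was tested.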

How the results depend on the processing

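Of the gene counts per comparison, 107 alternatives stayed within 1.5 times and 9 moved; of list counts 14 stayed and 10 moved, and of splicing counts 55 stayed and 11 moved. For named genes 5585 kept direction and side of the threshold, 48 became weaker, 7 stronger and 1 reversed. With an added 2-fold threshold the called genes were 1863 at D0, 1235 at D4, 3617 at D8, 10498 and 6310 for WT D4 and D8, 2557 and 3083 for the interactions and 7505 in nuclear RNA; fewer pass because the threshold is stricter. In nuclear RNA, 9136 were called among genes expressed in whole cells, a choice made after seeing the data. QKI at D8 reversed to -0.08 with total counts and to -0.04 without D8_WT replicate 4, and SESN2 in nuclear RNA to -0.04 with total counts (0.43 otherwise); the cause was not tested. With an estimated correlation the lists called were 2 at D0, 2 at D4, 0 at D8, 1 and 7 for WT, 0 and 0 for the interactions and 0 in nuclear RNA; with fry 22 at D8 and 23 for WT D4 against D0. Splicing calls at a difference of 0.2 were 642, 320, 857 and 93 (D0, D4, D8, 293T), with an absolute difference of at least 0.05 (splicing D0: events called) they were 3051, with no junction read minimum 1014 (splicing D4: events called) and 384 (293T), and with limma 213, 74, 390 and 50. The correlation of nuclear and whole-cell effects was 0.446 at 10 CPM and 0.252 by rank, against 0.285.

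Leaving out each replicate gave 7531 to 8432 genes at D0, 4874 to 5524 at D4, 10527 to 12017 at D8, 16619 to 21144 in nuclear RNA, 17234 to 17462 and 14044 to 14523 for WT, and 7515 to 8151 and 7942 to 9389 for the interactions. Splicing gave 1766 to 1851, 623 to 637, 1712 to 1801 and 197 to 203, and QKI -2.93 to -2.83, -1 to -0.81, -0.04 to 0.15 and, in nuclear RNA, 1.53 to 1.83. With the replicate block, genes called were 9153, 6172, 11136, 15666, 11656, 8476, 8891 and 18250, and lists 7, 13, 14, 14, 19, 9, 13 and 18, in the order D0, D4, D8, WT D4, WT D8, the interactions and nuclear RNA. Nuclear depth of 6549676 to 15030590 counts limits what low genes can show. Motif, splice site and inclusion-matched exon tests were not run.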

Other observations

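The tests in this part were set out before their results were seen, except where a sentence says otherwise. ZNF558 was the only gene under 0.5 CPM in the D8 libraries labelled KO with at least 10 in D8 WT and 5 in KO at D0 and D4, a rule chosen after its values were seen. It stood at 24.4 and 10.9 CPM in D0 WT and KO, 36.7 and 17.1 at D4, and 34.2 and 0.0113 at D8. In nuclear RNA the libraries labelled KO held 21.8, 27.6 and 24.3 CPM and WT 25.5, 24.7 and 24.5. Epithelial genes not in the fixed lists were lower at D8, among them KRT23 (-5.11), GRHL1 (-2.62) and GRHL2 (-2.08), named after their values were seen, and the test of their median (-0.92) left a change in cell share open.

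A first hypothesis was that exons called as changed keep the reading frame more often than unchanged ones, and it held in 4 of the authors' deposited tables. The share with a length divisible by 3 was 48.0 against 41.3% at D0 (odds ratio 1.31, Fisher's exact adjusted p 8.5e-06), 57.6 against 41.7% at D4 (1.9, 2e-12), 59.1 against 41.2% at D8 (2.06, 5.6e-30) and 61.7 against 41.2% in 293T (2.3, 5.5e-08).

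A second hypothesis was that the D8 libraries labelled KO come from cells in another epigenetic state, with imprinted genes changed 4-fold more often. The prediction left out MEG3 and NNAT, whose falls at D8 (-6.60 and at least 1030-fold) had been seen and would have added to the count. Without them it did not hold: 4 of 42 imprinted genes changed at D8 against 5.38% of other genes, a ratio of 1.77 (Fisher's exact p 0.29). At D0 the ratio was 1.43 (p 0.65) and at D4 1.26 (p 0.55). The test was first run with more filters than the prediction stated, on called genes at 1 CPM or more, and gave ratios of 10.7 at D0 (p 0.015, adjusted 0.045), 5.93 at D4 (p 0.16) and 2.46 at D8 (p 0.2). Single imprinted genes moved far at D8, such as MEG8 (-3.87), MEG9 (-5.46) and INPP5F (-2.61), named after their values were seen. NAP1L5, also named after its values were seen, held 1 count at D8 in the libraries labelled KO against 1613, a ratio of 1210 (95% counting interval 218 to 48000).

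Splits of 6 libraries number 10, too few for a share under 0.05. For genes, the real split alone reached its count (1 of 10) in D0, D4, D8, nuclear RNA and both WT comparisons, with a highest other of 0, 0, 1, 0, 0 and 0. For lists, 2, 1, 4, 2, 1 and 1 splits reached the real count, with a highest other of 6, 11, 16, 18, 14 and 15. For limma on inclusion, 1 of 10 did in each of the authors' deposited tables, with 213, 74, 390 and 50 events against a highest other of 10, 21, 16 and 25.

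Nuclear WT replicates 2 and 3 were closer than any other pair, with a reduced chi-square of 1.22 over 31671 genes, against 5.77 and 6.35 for the other nuclear WT pairs and 2.91 for the next closest pair. The labels do not say whether they are separate cultures; if they are not, nuclear WT holds 2 independent libraries and not 3. The 10 most abundant genes took 36.4% ± 4.4 of counts in nuclear WT and 25.7% ± 0.69 in nuclear KO. Genes of the mitochondrial genome took 7.56% of counts in D8 WT and 9.19% in the D8 libraries labelled KO.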
